A study of Mus musculus with 17 samples.

How the data were processed

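Gene expression was measured on 17 single-channel Affymetrix arrays, 1 per sample, from tibialis anterior muscle of 6 normal, 6 mdx and 5 fiona mice. Per the labels, the animals were males aged 56 days, muscles of both legs were pooled, and 8 µg of RNA was labelled per array. The deposited table holds log2 expression values per probe set. The submitters' processing notes name both RMA and GCRMA, and which of them made the deposited table is not given in the sources used here. The raw array images were not used here.

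Of 22690 probe sets, 64 Affymetrix control probe sets were set aside, 691 probe sets listed with several gene symbols and 1555 listed with none were left out of the tests across genes, and 20380 with exactly 1 symbol were kept. They covered 12393 genes, of which 4956 had more than 1 probe set. Each gene was represented by its probe set with the highest mean over all arrays. Gene identifiers of 12369 genes were found in the mouse reference gene table, and 0 symbols differed from the current symbol. No filter on level was applied, and no positions are given because the deposited files name no genome build. The array medians, the correlations between arrays and the control probe sets were checked. No pair of arrays was identical.

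Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values. A single fit held the means of the 3 groups. P values were adjusted by the Benjamini-Hochberg method over all 12393 genes, and a gene was called at an adjusted p under 0.05, with a second count for calls of at least 2-fold. Dmd and Utrn were tested on every probe set in a fit over all probe sets without controls, with two-sided exact permutation tests beside it. Differences are log2 values of the first group named minus the second, and values after ± are standard deviations unless marked SE. Where arrays of the dimmer group of a named gene lay at or under the array's median over 15 unspiked bacterial control probe sets, that median took the place of their values and the difference is given as at least that size, with the adjusted p of the fit to the deposited values; this rule was chosen after values were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

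Before the data were examined, 30 gene lists of pathways, muscle functions and markers of other cell types were fixed, together with the tests, the rule for named genes and most alternatives. Lists with at least 5 measured members, counted again after the filter on dim genes, were tested with camera at a preset correlation between genes of 0.01, adjusted over the 30 lists, and again with the correlation estimated from the data and with fry, which tests whether the genes of a list move, on balance, in 1 direction. A list called with fry alone is therefore not compared with other genes. Divisions of the arrays other than the real one also called many lists with the preset correlation. Their medians were 8 for mdx against normal, 7 for fiona against mdx and 6 for fiona against normal. The real counts were 16, 17 and 10. With an estimated correlation, the calls that held were macrophage, lysosome and regeneration for mdx against normal, macrophage, lysosome and matrix proteases with TGF-beta signalling for fiona against mdx, and 0 lists for fiona against normal. The genes Chrng, Tnc, Ctsl and Egr2 stand in more than 1 list.

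The rule for named genes took Dmd and Utrn in every comparison, the 8 called genes with the largest increase and the 8 with the largest decrease per comparison, and up to 3 called members per list with the largest change, or the member with the smallest p for a list with 0 calls. The rule allowed fewer list members to be named. List members were left out for length, and after the values were seen, some whose call depended on single arrays were also left out as list members: Nos1, Cd74 and Sdha for mdx against normal, and Cd74, Cox6a2 and Nr1d2 for fiona against mdx. Pdk4 was kept for mdx against normal, although its call also depended on single arrays. The genes Rragd, Cyp2e1, Asb15 and Glul fall outside the rule and were chosen after their values were seen.

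The share of the mdx change reversed in fiona was measured by selecting genes on 3 mdx and 3 normal arrays (adjusted p under 0.05, at least 2-fold) and summing their signed differences on the other mdx and normal arrays and all fiona arrays. This was repeated for 100 random divisions of the arrays, which selected between 1 and 402 genes. Opposite calls in both comparisons were counted, and set against independent draws (27.1 and 57.4 genes for the 2 directions), against 100 simulations in which fiona arrays were drawn as mdx arrays, and against fits that used different mdx arrays for each comparison.

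The array sets were defined from the data, as the sign of the largest component of the residuals from the group means, and no label gives a batch. Set 1 held normal arrays 3, 4 and 5, mdx arrays 3, 4 and 5 and fiona arrays 1 and 4, and set 2 held the other 9 arrays. The sex pattern was read from Eif2s3y, at the midpoint of its range, and compared with Xist. Counts were repeated with the array set as a block, within each set, and with the sex pattern as a covariate. These alternatives, and those with both covariates, with a block on array number for mdx and normal arrays alone, and with the set block but without mdx array 1, were chosen after seeing the data. The alternatives fixed earlier were a filter on dim genes at the median of all probe sets (3.67), the mean of a gene's probe sets, every probe set tested, an intensity trend with a robust prior, median-centring, quantile normalization, array weights, a block on array number, an adjusted p under 0.01, fits of the compared groups alone, a floor at the 5th percentile (1.92) and leaving out each array in turn.

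The procedures were tested on simulated data, with noise drawn independently for each gene and without array sets. The false calls given here are therefore no measure of those in the real arrays. For mdx against normal, 76% of 100 genes changed 2-fold and 99% of 100 genes changed 4-fold were called, with 9 false calls among 12393 genes. For fiona against mdx, 42% of 100 genes changed 1.41-fold and 77% of 100 genes changed 2-fold were called, with 10 false calls. A reversed share of 0.5 built into simulated data was estimated as 0.490. The number of arrays limits the precision of every estimate.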

Results

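Gene expression was measured in the tibialis anterior, a fast muscle of the lower leg, of mice aged 56 days on 17 Affymetrix expression arrays. Of these, 6 arrays held normal muscle and 6 held muscle of mdx mice, which carry a mutation in the dystrophin gene. The remaining 5 arrays held muscle of fiona mice, which are mdx mice with a transgene for utrophin, a protein related to dystrophin. Each array was labelled as a biological replicate, and the number of arrays limits the precision of every value. The array medians of the deposited log2 values lay between 3.52 and 3.82, and the correlations between pairs of arrays lay between 0.939 and 0.996. After removal of the group means, the arrays fell into 2 sets along the largest component, which held 42.7% of the remaining variance. Set 1 comprised 3 normal, 3 mdx and 2 fiona arrays, and set 2 comprised 3 normal, 3 mdx and 3 fiona arrays. The labels give male animals throughout, but 7 arrays had a female pattern of Xist, the transcript of X inactivation, and Eif2s3y, a gene of the Y chromosome. Those arrays were 1 normal, 2 mdx and 4 fiona arrays. Xist was read on its probe set with the largest range. Another Xist probe set did not show the pattern in fiona array 2 and mdx array 1.

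Dystrophin and utrophin transcripts, which define the 3 groups, differed between them in the direction given by the labels. Dmd, the dystrophin gene, was lower in mdx and fiona muscle on both of its probe sets that had signal in normal muscle. On the second brightest of its 3 probe sets, which had the smaller spread, Dmd measured 6.64 ± 0.20 in normal muscle (SD, n = 6), 3.35 ± 0.10 in mdx muscle (n = 6) and 3.39 ± 0.14 in fiona muscle (n = 5). The 9.75-fold difference between mdx and normal muscle had an adjusted p of 4.32e-12 in limma and an exact permutation p of 0.00216, two-sided, the smallest these group sizes allow. On the brightest Dmd probe set, the levels were 8.34 ± 0.77 in normal, 5.33 ± 0.77 in mdx and 5.04 ± 1.05 in fiona muscle. The dimmest Dmd probe set measured 3.10 in normal, 2.99 in mdx and 3.28 in fiona muscle and carried little signal.

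Utrn, the utrophin gene, measured 2.12 ± 0.04 in normal, 2.07 ± 0.02 in mdx and 4.30 ± 1.90 in fiona muscle on the dimmest of its 3 probe sets. All normal and mdx arrays and 1 fiona array lay at or under the level of the unspiked bacterial controls. Differences are given as lower bounds, against that level. The log2 difference between fiona and mdx muscle was at least 1.61 (adjusted p = 0.0126 in limma). Above the control level lay 4 of 5 fiona and 0 of 6 mdx arrays (exact permutation p = 0.0152, two-sided, with values at or under that level set to it). Within the array sets the difference was at least 3.44 in set 1 and at least 0.38 in set 2. On the second brightest Utrn probe set, with all mdx arrays and 1 fiona array at or under the control level, the difference was at least 1.83 (adjusted p = 0.0262), and at least 4.03 in set 1 and 0.36 in set 2. Its call was lost without fiona array 1 (adjusted p = 0.0689) or fiona array 4 (adjusted p = 0.0556), and with median-centred arrays (adjusted p = 0.0782) or quantile normalization (adjusted p = 0.0735). The brightest Utrn probe set did not follow the transgene and measured 6.81 ± 0.26 in normal, 6.98 ± 0.39 in mdx and 6.57 ± 0.82 in fiona muscle. That probe set represents Utrn in the tests across genes, where the log2 difference between fiona and mdx muscle was -0.41 (adjusted p = 0.307).

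**Figure D1:**
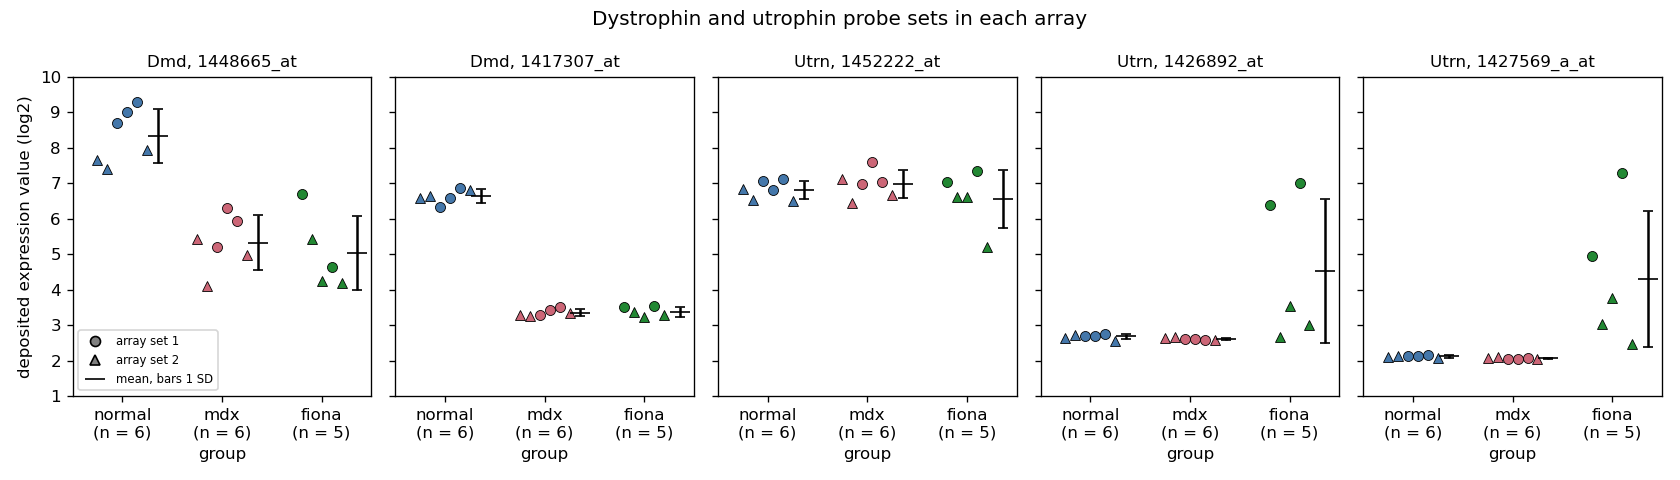
Deposited log2 expression value (vertical axis) of the Dmd and Utrn probe sets with signal in any group, by group (horizontal axis), with points for single arrays, shapes for the 2 array sets, lines for means and bars for 1 SD. Dmd lies lower in mdx and fiona than in normal muscle on both of its probe sets, and the second brightest and dimmest Utrn probe sets, in the last panels, rise in fiona muscle, by more in array set 1 than in array set 2.

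The comparison of mdx with normal muscle addressed what the lack of dystrophin did to gene expression. The lists of macrophage (22 of 29 rose), lysosomal (10 of 18) and regeneration genes (10 of 28) were called higher in mdx muscle with a preset and with an estimated correlation between genes. With the preset correlation the fibrillar matrix list was also called higher (11 of 29 rose; adjusted p = 0.0562 with an estimated correlation). The lists of fatty acid oxidation (4 of 20 fell; adjusted p = 0.0552 with an estimated correlation) and of the TCA cycle and respiratory chain (4 of 30 fell; adjusted p = 0.0975 with an estimated correlation) were called lower with it. Lgals3, a galectin abundant in macrophages, had the largest measured increase, 65.5-fold, from 5.43 ± 0.66 in normal to 11.5 ± 0.66 in mdx muscle (SD, n = 6 each, adjusted p = 1.82e-07 in limma). Myh3, the embryonic myosin heavy chain, rose 42.9-fold from 4.95 ± 0.41 to 10.4 ± 1.19 (adjusted p = 2.55e-06). The other genes with the largest increases were the macrophage genes Mpeg1 (41.0-fold), Tyrobp (39.7-fold) and Gpnmb (at least 31.0-fold, with 6 of 6 normal arrays at or under the control level), the embryonic and atrial myosin light chain Myl4 (37.0-fold), the cardiac troponin T gene Tnnt2 (32.4-fold), which is also expressed in developing muscle, and Sln (at least 24.98-fold, with 5 of 6 normal arrays at or under that level), which encodes an inhibitor of the sarcoplasmic calcium pump. Bdh1, an enzyme of ketone body metabolism, fell most, at least 13.4-fold, from 7.13 ± 0.48 to 3.25 ± 0.87 (2 of 6 mdx arrays at or under the control level, adjusted p = 0.000130). It was followed by Dmd (8.04-fold lower), the slow myosin light chain Myl3 (6.64-fold lower), the phosphatase Dusp26 (6.01-fold lower), the fast oxidative myosin Myh2 (5.29-fold lower), Chac1 (4.49-fold lower), which degrades glutathione, the mitochondrial carrier Ucp3 (3.77-fold lower) and the carboxylesterase Ces1d (3.71-fold lower). All of these genes had 6 of 6 mdx arrays on the side of the change relative to the normal mean. They were selected on these same arrays, so this is not a separate test. All 6 mdx arrays lay beyond every normal array, except for Myl3 and Ucp3 with 5. The call of Myh2 was lost when any of mdx arrays 2, 3 and 5 or normal arrays 3, 4, 5 and 6 was left out, with adjusted p up to 0.0699 and log2 differences between -2.42 and -1.99.

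Among lists of immune genes, 22 of 29 measured macrophage genes rose and 0 fell (25 rose adjusted over the list alone), with a median log2 difference of 2.74 (camera adjusted p = 2.42e-45, and adjusted p = 0.00175 with an estimated correlation). Of 22 chemokines and receptors, 4 rose (7 adjusted over the list alone), among them Ccl8, a chemokine for monocytes (log2 difference 3.11; list adjusted p = 4.42e-05, and adjusted p = 0.0787 with an estimated correlation). Of 17 genes of complement and antigen presentation, 6 rose (9 adjusted over the list alone), such as H2-Aa, a chain of MHC class II (1.96; list adjusted p = 3.23e-09, and adjusted p = 0.0562 with an estimated correlation). Of 15 interferon-induced genes, 1 rose (1 adjusted over the list alone), and the list median was 0.63 (adjusted p = 0.000130, and adjusted p = 0.302 with an estimated correlation). Of 18 lysosomal genes, 10 rose (12 adjusted over the list alone), including the proteases Lgmn (3.07) and Ctsh (2.60), and this list was called with the preset correlation (adjusted p = 6.61e-17) and with an estimated one (adjusted p = 0.00562 with an estimated correlation).

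Among matrix genes, 11 of 29 genes of fibrillar collagen and matrix rose (18 adjusted over the list alone, with 1 lower), such as Postn, encoding periostin (log2 difference 2.77), and the collagen VI gene Col6a2 (2.11). The list median was 1.30 (adjusted p = 5.45e-16, and adjusted p = 0.0562 with an estimated correlation). Of 22 genes of matrix proteases and TGF-beta signalling, 5 rose and 1 fell (6 and 1 adjusted over the list alone). The protease inhibitor Timp1 rose by at least 4.37 and the metalloprotease Adam8 by 2.16 (list adjusted p = 0.000253, and adjusted p = 0.0547 with an estimated correlation). Of 12 tendon and cartilage genes, 1 rose (4 adjusted over the list alone), the joint lubricant gene Prg4 (3.27; list adjusted p = 0.0271, and adjusted p = 0.405 with an estimated correlation). The tendon and cartilage list was not called without mdx array 6 (adjusted p = 0.0730), normal array 2 (0.0875) or normal array 5 (0.0983).

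Among muscle genes, 10 of 28 regeneration genes rose (15 adjusted over the list alone), with a median of 0.89 (adjusted p = 7.97e-14, and adjusted p = 0.0166 with an estimated correlation). Of 29 cell cycle genes, 3 rose (4 adjusted over the list alone), including Rrm2, a subunit of the enzyme that makes deoxynucleotides (log2 difference 3.99), and the replication clamp Pcna (0.90). The cell cycle median was 0.05 (list adjusted p = 1.69e-05, and adjusted p = 0.0975 with an estimated correlation). Of 15 neuromuscular junction genes, 3 rose (4 adjusted over the list alone), led by Chrna1, the alpha subunit of the acetylcholine receptor (3.08; list adjusted p = 0.00295, and adjusted p = 0.0562 with an estimated correlation). Of 14 slow fibre genes, 3 rose and 1 fell (7 and 4 adjusted over the list alone), with the slow troponin I gene Tnni1 higher by 4.16 and Myl3 lower (list adjusted p = 0.0187, and adjusted p = 0.341 with an estimated correlation). The slow fibre list was not called without mdx array 4 (adjusted p = 0.0710) or normal array 2 (0.0584), nor with quantile normalization (0.0540). In the dystrophin complex list, 1 of 19 genes rose and 1 fell (3 and 1 adjusted over the list alone), and the muscle caveolin gene Cav3 rose by 1.11. That list was not called (adjusted p = 0.0655), but was called without mdx array 1 (0.0257) or mdx array 2 (0.0487).

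Among metabolic genes, 4 of 20 genes of fatty acid oxidation fell and 0 rose (8 adjusted over the list alone), with a median of -0.60 (adjusted p = 1.51e-06, and adjusted p = 0.0552 with an estimated correlation). They included Lpl, which releases fatty acids from lipoproteins (log2 difference -1.17), and Pdk4, an inhibitor of pyruvate dehydrogenase (-1.63). The Pdk4 call was lost without mdx array 4 or normal array 3, 4 or 5, with adjusted p up to 0.0536. Of 30 genes of the TCA cycle and respiratory chain, 4 fell (9 adjusted over the list alone), such as fumarate hydratase, Fh1 (-0.39; list adjusted p = 0.000186, and adjusted p = 0.0975 with an estimated correlation). Of 19 genes of glycolysis and glycogen, 2 fell (4 adjusted over the list alone, with 1 higher), including the lactate dehydrogenase subunit Ldhb (-1.59), and the list was not called (adjusted p = 0.275). Of 12 adipocyte genes, 2 fell (3 adjusted over the list alone, with 1 higher), the lipid synthesis genes Dgat2 (-1.64) and Scd1 (-1.53), and the list was not called (adjusted p = 0.192). Of 17 genes of oxidative and metal stress, 4 rose (4 adjusted over the list alone, with 1 lower), including the metallothioneins Mt2 (3.92) and Mt1 (3.14; list adjusted p = 0.00689, and adjusted p = 0.215 with an estimated correlation). Of 16 circadian clock genes, 1 fell (2 adjusted over the list alone), the repressor Nr1d2 (-1.04; list adjusted p = 0.0229, and adjusted p = 0.0562 with an estimated correlation). The clock list was not called without normal array 6 (adjusted p = 0.0648).

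The other 11 lists were not called between mdx and normal muscle. Among their members 4 rose and 3 fell (4 and 5 adjusted over the list alone). Their adjusted p was 0.0779 for immediate early, 0.143 for lymphocyte, 0.257 for fast fibre, 0.278 for smooth muscle and pericyte, and 0.281 for both epidermis and Schwann cell and nerve. It was 0.367 for endothelial, 0.389 for neutrophil, eosinophil and mast cell, 0.451 for atrophy and autophagy, 0.476 for erythroid and 0.933 for calcium handling genes. The atrophy and autophagy list had a median of -0.04 and a mean of -0.02, while its test pointed upward. Leaving out 1 array led to a call of the lymphocyte list (without mdx array 2, adjusted p = 0.0487), the immediate early list (without mdx array 4, 0.0275), and the fast fibre (0.0290) and glycolysis and glycogen (0.0382) lists (both without normal array 5). With the filter on dim genes the slow fibre (0.0739), oxidative and metal stress (0.105) and tendon and cartilage (0.0984) lists were not called and the adipocyte list was (0.0212). With fry the interferon-induced (0.129), slow fibre (0.0802) and tendon and cartilage (0.185) lists were not called and the adipocyte (0.0211) and smooth muscle and pericyte (0.0327) lists were. The immediate early list was called with the mean of probe sets (0.0349) and with a block on array number (0.0173). With that block the calls of Myh2 (adjusted p = 0.0882), Chac1 (0.0674), Pcna (0.0534), Pdk4 (0.0504) and Scd1 (0.0554) were lost.

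Across all 12393 genes tested with limma, 578 differed between mdx and normal muscle at an adjusted p under 0.05, of which 399 were higher and 179 lower in mdx muscle. At least 2-fold differences were found for 335 of them, 279 higher and 56 lower. With array set as a block, 1238 genes passed, 710 higher and 528 lower. In array set 1 alone 2565 genes passed (689 higher, 1876 lower), and in array set 2 alone 272 passed (172 higher, 100 lower). All 335 genes with at least 2-fold differences had the same sign in both array sets, and all of them were called with the block. They were selected on these same arrays, so this agreement is not a separate test. In array set 1 alone 274 of them were called in the same direction, and in array set 2 alone 133.

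The comparison of fiona with mdx muscle addressed what raised utrophin changed in muscle that lacks dystrophin. The lists of macrophage (23 of 29 fell), lysosomal (12 of 18) and matrix protease and TGF-beta genes (10 of 22 fell and 1 rose) were called lower in fiona than in mdx muscle with a preset and with an estimated correlation. The fibrillar matrix list (19 of 29 fell; adjusted p = 0.0940 with an estimated correlation) and the regeneration list (13 of 28 fell and 5 rose; adjusted p = 0.0791 with an estimated correlation) were called lower with the preset correlation. Gpnmb fell at least 28.4-fold, from 7.72 ± 0.99 in mdx (SD, n = 6) to 2.56 ± 0.12 in fiona muscle (n = 5, all at or under the level of the unspiked controls, adjusted p = 5.27e-07 in limma). Other large decreases were those of Tyrobp (34.8-fold lower), Lgals3 (30.5-fold lower), Myl4 (25.6-fold lower), Tnnt2 (25.4-fold lower), Myh3 (22.4-fold lower), Timp1 (at least 19.01-fold lower, 5 of 5 fiona arrays at or under that level) and Sln (at least 18.0-fold lower, 4 of 5 fiona arrays). Bdh1 rose most, at least 7.52-fold, from 3.25 ± 0.87 to 6.29 ± 1.16 (2 of 6 mdx arrays at or under that level, adjusted p = 0.00226), followed by Myh2 (5.92-fold), Dusp26 (4.50-fold), the synaptic and muscle scaffold Homer2 (3.95-fold), Nos1, the neuronal nitric oxide synthase of the dystrophin complex (3.83-fold), Myl3 (3.76-fold), the oxygen-sensing hydroxylase Egln3 (3.34-fold) and the transcriptional regulator Dach2 (2.76-fold). All of these genes had 5 of 5 fiona arrays on the side of the change relative to the mdx mean, except Nos1 with 4. They were selected on these same arrays, so this is not a separate test. All 5 fiona arrays lay beyond every mdx array, except for Bdh1, Myh2, Nos1 and Egln3 with 4 and Myl3 with 3. The Egln3 call was lost when fiona array 1, 2 or 5 or mdx array 3, 4 or 5 was left out (adjusted p up to 0.0614), with median-centred arrays (0.0831) and with the sex pattern in the model (0.0870). The Dach2 call was lost without fiona array 1 or 4 or mdx array 5 (adjusted p up to 0.0720), with median-centred arrays (0.0884) and with quantile normalization (0.0757).

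Of 29 macrophage genes, 23 fell and 0 rose between mdx and fiona muscle (24 and 1 adjusted over the list alone), with a median of -2.50 (camera adjusted p = 3.96e-30, and adjusted p = 0.0123 with an estimated correlation). Of 18 lysosomal genes, 12 fell (13 adjusted over the list alone), including Lgmn (log2 difference -2.85) and Ctsh (-2.70; list adjusted p = 4.89e-13, and adjusted p = 0.0150 with an estimated correlation). Of 22 chemokines and receptors, 6 fell and 3 rose (6 and 3 adjusted over the list alone), and Ccl8 fell by 3.16 (list adjusted p = 0.00174, and adjusted p = 0.199 with an estimated correlation). Of 17 genes of complement and antigen presentation, 8 fell and 2 rose (9 and 2 adjusted over the list alone), such as the MHC class II gene H2-Ab1 (-1.36; list adjusted p = 1.45e-06, and adjusted p = 0.143 with an estimated correlation). Of 15 interferon-induced genes, 3 fell and 1 rose (2 and 1 adjusted over the list alone; list adjusted p = 0.000408, and adjusted p = 0.356 with an estimated correlation). Of 21 lymphocyte genes, 15 rose (17 adjusted over the list alone) with the deposited values and 2 with median-centred arrays, at medians of 0.13 and 0.01. Unspiked bacterial controls were 0.164 higher in fiona than in mdx arrays. Ms4a1, which encodes the B cell antigen CD20, rose by 0.67. The lymphocyte list had an adjusted p of 0.00190, and adjusted p = 0.505 with an estimated correlation, and was not called with quantile normalization (0.372).

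Of 29 genes of fibrillar collagen and matrix, 19 fell (22 adjusted over the list alone), including Postn (log2 difference -2.53), Col14a1, which encodes collagen XIV (-2.53), and the collagen cross-linking enzyme Lox (-2.13; list adjusted p = 1.17e-15, and adjusted p = 0.0940 with an estimated correlation). Of 22 genes of matrix proteases and TGF-beta signalling, 10 fell and 1 rose (10 and 1 adjusted over the list alone), among them Adam8 (-2.09; list adjusted p = 4.78e-06, and adjusted p = 0.0150 with an estimated correlation). Of 12 tendon and cartilage genes, 4 fell (4 adjusted over the list alone), such as Prg4 (-3.29) and the matrix glycoprotein gene Tnc (-2.01; list adjusted p = 0.000408, and adjusted p = 0.199 with an estimated correlation).

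Of 28 regeneration genes, 13 fell and 5 rose (13 and 6 adjusted over the list alone), with a median of -0.82 (adjusted p = 3.14e-08, and adjusted p = 0.0791 with an estimated correlation). Of 14 slow fibre genes, 6 fell and 4 rose (6 and 5 adjusted over the list alone), with Tnni1 (log2 difference -4.44) and the slow troponin C gene Tnnc1 (-2.73) lower (list adjusted p = 0.00973, and adjusted p = 0.309 with an estimated correlation). Of 15 neuromuscular junction genes, 4 fell and 3 rose (4 and 3 adjusted over the list alone), and Chrna1 fell by 2.71 (list adjusted p = 0.0401, and adjusted p = 0.199 with an estimated correlation). The junction list was not called without fiona array 1 (adjusted p = 0.0740), fiona array 2 (0.0772), fiona array 4 (0.113) or mdx array 6 (0.0555). Of 29 cell cycle genes, 4 fell and 6 rose (4 and 6 adjusted over the list alone), with Rrm2 (-3.84) and Pcna (-0.91) lower. The cell cycle list had a median of 0.05, which was -0.08 with median-centred arrays, a mean of -0.24 and a test that pointed down (adjusted p = 0.0401, and adjusted p = 0.505 with an estimated correlation). It was not called without fiona array 1 (0.0970), fiona array 2 (0.118), fiona array 4 (0.0695) or mdx array 4 (0.0770), nor with the array set block (0.0635). Of 19 dystrophin complex genes, 3 fell and 4 rose (3 and 4 adjusted over the list alone), and the laminin gene Lama2 fell by 1.11. That list was not called (adjusted p = 0.0823) unless fiona array 3 (0.0486), fiona array 5 (0.0405) or mdx array 1 (0.0422) was left out.

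Of 17 genes of oxidative and metal stress, 4 fell and 1 rose (4 and 1 adjusted over the list alone), and Mt2 fell by 4.08 (list adjusted p = 0.000241, and adjusted p = 0.143 with an estimated correlation). Of 20 immediate early genes, 1 fell and 3 rose (1 and 3 adjusted over the list alone), with a median of -0.47 (adjusted p = 0.0102, and adjusted p = 0.309 with an estimated correlation). Of 15 atrophy and autophagy genes, 4 fell and 2 rose (4 and 3 adjusted over the list alone; adjusted p = 0.0196, and adjusted p = 0.143 with an estimated correlation), and the call was lost with quantile normalization (0.224). Of 12 epidermis genes, 8 rose (8 adjusted over the list alone) with the deposited values and 2 with median-centred arrays, at medians of 0.14 and 0.02, beside the 0.164 of the unspiked controls. The epidermis list had an adjusted p of 0.0221, and adjusted p = 0.520 with an estimated correlation, and its call was also lost with quantile normalization (0.111). Of 30 genes of the TCA cycle and respiratory chain, 9 rose (9 adjusted over the list alone), such as Sdhb, a subunit of succinate dehydrogenase (0.49), whose call was lost with median-centred arrays (0.37, adjusted p = 0.115). That list was not called (adjusted p = 0.0954, and adjusted p = 0.505 with an estimated correlation) but was called with the array set block (0.01), with quantile normalization (0.00117), with the filter on dim genes (7.40e-05), with fry (0.00141) and with a block on array number (0.0224). Over all 12393 genes, 3977 rose with the deposited values. Of 20 genes of fatty acid oxidation, 4 rose (2 adjusted over the list alone), including Lpl (1.01) and the acyl-CoA dehydrogenase Acadvl (0.76). The fatty acid oxidation list was not called (adjusted p = 0.541, and adjusted p = 0.832 with an estimated correlation), but was called with quantile normalization (0.0116), with the filter on dim genes (0.00515) and with fry (0.0156). With median-centred arrays fewer list members rose, such as 0 regeneration genes where 5 had risen, 1 cell cycle gene of 6, and 1 TCA cycle and respiratory chain gene of 9. With quantile normalization 2 regeneration, 2 cell cycle and 9 TCA cycle and respiratory chain genes rose.

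The other 10 lists were not called between fiona and mdx muscle. Among their members 22 rose and 3 fell (20 and 2 adjusted over the list alone) with the deposited values, and 6 rose and 2 fell with median-centred arrays. Ldhb rose by 1.32 and Dgat2 by 1.35. The adjusted p was 0.463 for erythroid, 0.533 for both calcium handling and neutrophil, eosinophil and mast cell, and 0.655 for adipocyte genes. It was 0.833 for glycolysis and glycogen, for endothelial and for Schwann cell and nerve genes, 0.918 for smooth muscle and pericyte, 0.944 for circadian clock and 0.957 for fast fibre genes. Medians were above 0 and the test pointed down for the calcium handling (0.15), glycolysis and glycogen (0.10), endothelial (0.22), smooth muscle and pericyte (0.14) and adipocyte (0.04) lists, the last with a mean of -0.03. With median-centred arrays the medians of the glycolysis and glycogen (-0.02) and adipocyte (-0.08) lists were below 0. With the filter on dim genes the cell cycle (adjusted p = 0.437), slow fibre (0.222) and atrophy and autophagy (0.240) lists were not called. With fry the junction (0.185), chemokine (0.110), interferon-induced (0.164), cell cycle (0.162), slow fibre (0.0816), atrophy and autophagy (0.0816) and immediate early (0.317) lists were not called. The circadian clock (0.00351) and erythroid (0.00579) lists were called with fry. With a block on array number the calls of Nos1 (0.0534), Dach2 (0.0675), H2-Ab1 (0.0568), Tnc (0.0515) and, each at 0.0507, Myh2, Myl3, Lama2, Lox, Pcna, Sdhb and Ms4a1 were lost.

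Across the 12393 genes tested with limma, 4818 differed between fiona and mdx muscle at an adjusted p under 0.05, with 3977 higher and 841 lower in fiona muscle. At least 2-fold differences were found for 438 of them, with 29 higher and 409 lower. The median log2 difference of all genes was 0.08, and median-centring of the arrays moved it to -0.04, and the sizes of small changes are to be read relative to this shift. With median-centred arrays 654 genes were higher and 784 lower, with quantile normalization 1336 were higher and 569 lower, and among the brighter genes alone 346 were higher and 546 lower. With array set as a block 5398 genes passed (4223 higher, 1175 lower), in array set 1 alone 4295 passed (3498 higher, 797 lower), and in array set 2 alone 110 passed (13 higher, 97 lower). The genes with at least 2-fold differences had the same sign in both sets in all 438 cases, but they were selected on these same arrays. In array set 1 alone 348 of them were called in the same direction, and in array set 2 alone 74. Without fiona array 5 the number of called genes was 3191.

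Genes changed in mdx muscle were compared with those changed by utrophin. Of the 578 genes called between mdx and normal muscle, 454 were called in the opposite direction between fiona and mdx muscle and 0 in the same direction. Of these, 373 were higher in mdx and lower in fiona, and 81 were lower in mdx and higher in fiona, where independent draws give 27.1 and 57.4. Because both comparisons share the mdx arrays, the count was set against 100 simulations with fiona arrays drawn as mdx arrays, in which the median count was 0 and the highest was 2. These simulations drew noise independently for each gene and without array sets, so they understate the spread of such counts. Regrouping the real mdx and fiona arrays gave up to 143 opposite calls. Dividing the mdx arrays, 3 for each comparison, gave a median of 156.5 (range 133 to 264) opposite calls over 20 divisions. With array set as a block 868 genes were called in opposite directions, in array set 1 alone 2138, and in array set 2 alone 93. At the level of at least 2-fold, 258 of 335 genes were called in opposite directions at that size, 244 of 279 higher in mdx and 14 of 56 lower in mdx, where independent draws give 9.21 and 0.131. The fiona mean lay closer to the normal than to the mdx mean for 275 of the 279 genes higher in mdx muscle and for 31 of the 56 lower genes. The 56 lower genes include Dmd, the mutated gene.

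The share of the mdx change that was reversed in fiona muscle was measured on arrays not used to select the genes. Its median over 100 divisions of the arrays was 0.906 (quartiles 0.885 and 0.953, range 0.740 to 1.49), where 0 is the mdx level and 1 the normal level. With array set as a block it was 0.884. For genes higher in mdx muscle the share was 0.931 (range 0.856 to 1.27). For genes lower in mdx muscle, of which 88 of the 100 divisions selected any, it was 0.610 (quartiles 0.507 and 0.708, range -3.35 to 1.502), or 0.563 with the block (96 divisions, range 0.222 to 0.757). Dmd, the mutated gene, was not left out of the lower genes. Its log2 differences from normal muscle were -3.01 in mdx and -3.30 in fiona muscle. The share without Dmd was not computed. On a scale from 0 for the normal mean to 1 for the mdx mean, with the array set effect removed, fiona arrays lay at 0.11 ± 0.09 (SD, n = 5), normal arrays at 0.00 ± 0.07 (n = 6) and mdx arrays at 1.00 ± 0.14 (n = 6).

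**Figure D2:**
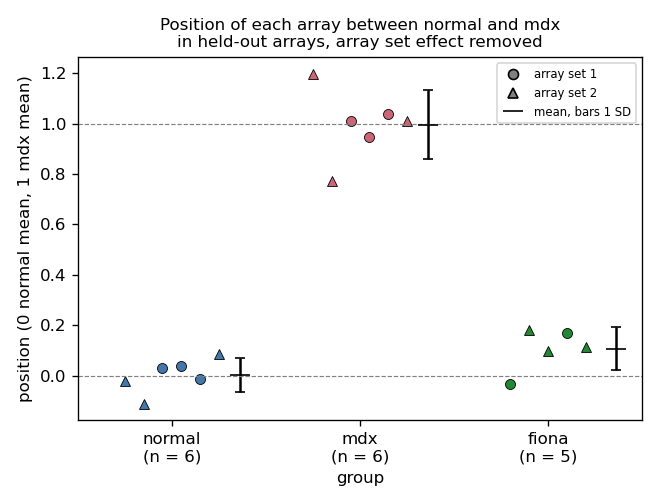
Position of each array (vertical axis, no unit) between the normal mean at 0 and the mdx mean at 1 over genes selected on other arrays, by group (horizontal axis), with the array set effect removed, points for arrays and bars for 1 SD around the mean. Fiona arrays lie between -0.03 and 0.18, and mdx arrays between 0.77 and 1.20.

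The comparison of fiona with normal muscle addressed which differences from normal muscle remained with utrophin. No gene passed the limma test across genes, in which 2626 genes had an unadjusted p under 0.05, although Dmd measured far lower in fiona muscle. On the second brightest Dmd probe set fiona muscle was 9.52-fold lower than normal muscle (adjusted p = 1.03e-11 over all probe sets). In the test across genes, Dmd was represented by its brightest probe set and had the smallest adjusted p, 0.106, at a log2 difference of -3.30. It was called without fiona array 1 (adjusted p = 0.00394) or fiona array 2 (0.0345) and with the array set block (0.00478). All other genes named for this comparison except Utrn had an adjusted p of 0.210. The largest differences among them were those of Adipoq, the fat cell hormone adiponectin (lower by at least 2.74, with 1 of 5 fiona arrays at or under the control level), the mitochondrial carrier Ucp3 (-1.98 ± 0.45, SE), the junctional membrane protein gene Jph1 (-1.57 ± 0.51), the immediate early gene Nr4a1 (-1.16 ± 0.34) and the protease inhibitor Timp3 (-1.10 ± 0.32). The macrophage gene Mpeg1 (0.95 ± 0.32) and Ankrd1, a gene raised in regenerating muscle (0.93 ± 0.28), lay higher in fiona muscle. The differences were -0.85 for the proteoglycan gene Dcn, 0.61 for the muscle LIM protein gene Fhl1, -0.56 for the clock gene Nr1d2, -0.24 for Utrn (adjusted p = 0.661) and 0.18 for the fast myosin Myh1. Without fiona array 2, the genes Ucp3, Adipoq, Mpeg1, Timp3, Fhl1 and Myh1 were called, with adjusted p between 0.0434 and 0.0486.

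Gene lists gave 10 calls between fiona and normal muscle with the preset correlation, 0 with an estimated correlation and 0 with fry, and no list had a member that passed over all genes. Fatty acid oxidation was lower, with a median of -0.23 (0 members lower over all genes and 2 adjusted over the list alone; adjusted p = 2.44e-05, and adjusted p = 0.102 with an estimated correlation). The circadian clock list, with a median of -0.15, had an adjusted p of 0.00894, and adjusted p = 0.102 with an estimated correlation. The atrophy and autophagy list, at -0.22, had an adjusted p of 0.00629, and adjusted p = 0.102 with an estimated correlation. Fibrillar collagen and matrix, at -0.12, had an adjusted p of 0.00429, and adjusted p = 0.585 with an estimated correlation. Matrix proteases and TGF-beta signalling had a median of 0.04 and a mean of -0.23 with a test that pointed down (adjusted p = 0.00429, and adjusted p = 0.102 with an estimated correlation), and the median was -0.06 with median-centred arrays. The tendon and cartilage list, at -0.31, had an adjusted p of 0.00700, and adjusted p = 0.514 with an estimated correlation. The adipocyte list, at -0.08 with 2 members lower adjusted over the list alone, had an adjusted p of 0.0147, and adjusted p = 0.264 with an estimated correlation. Oxidative and metal stress, at -0.06, had an adjusted p of 0.0231, and adjusted p = 0.514 with an estimated correlation. The lymphocyte list, at 0.10, had an adjusted p of 0.00429, and the epidermis list, at 0.13 with 1 member higher adjusted over the list alone, had 0.0192, each with adjusted p = 0.585 with an estimated correlation, and their medians were 0.01 and 0.04 with median-centred arrays. With quantile normalization 1 list was called, fatty acid oxidation, and the other 9 had adjusted p between 0.0605 and 0.473. With the filter on dim genes 5 lists were called. Fatty acid oxidation (adjusted p = 0.0121) and adipocyte genes (0.0149) were lower, and macrophage (median 0.30, 0.00737), cell cycle (0.23, 0.00737) and regeneration genes (0.27, 0.0163) were higher. The lymphocyte and epidermis lists were not tested there, and the other 6 had adjusted p between 0.0784 and 0.868.

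Leaving out single arrays ended list calls between fiona and normal muscle. Without fiona array 1 the fibrillar collagen and matrix (adjusted p = 0.291), oxidative and metal stress (0.0823), adipocyte (0.0525) and tendon and cartilage (0.0838) lists were not called. The oxidative and metal stress list was not called without fiona array 4 (0.0513), mdx array 1 (0.0539) or normal array 4 (0.0520), the tendon and cartilage list without normal array 3 (0.0546), and the adipocyte list without normal array 5 (0.0634). The macrophage (median 0.19, adjusted p = 0.868), regeneration (0.14, 0.650), lysosome (-0.06, 0.113) and cell cycle (0.15, 0.115) lists were not called between fiona and normal muscle with all genes tested, and the lysosome median was 0.07 with quantile normalization. The lysosome list was called without fiona array 2 (0.0346), fiona array 5 (0.0445) or normal array 5 (0.0250), with the mean of probe sets (0.0329) and with the sex pattern in the model (0.0347). With the sex pattern in the model the interferon-induced (2.31e-05), slow fibre (0.00334), endothelial (0.00334) and immediate early (0.0347) lists were also called and the oxidative and metal stress list was not (0.0547). The endothelial list was called with the array set block (0.0489). The remaining 16 lists had an adjusted p between 0.0643, for glycolysis and glycogen, and 0.809. Of these, glycolysis and glycogen, TCA cycle and respiratory chain, endothelial, fast fibre, calcium handling and immediate early were called without at least 1 of fiona arrays 1, 2, 3 and 5 and normal arrays 3, 4 and 5, with adjusted p between 0.00737 and 0.0449.

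Among the remaining lists, the dystrophin complex, chemokine, complement and antigen presentation, interferon-induced, fast fibre, TCA cycle and respiratory chain, immediate early and Schwann cell lists had medians above 0 with tests that pointed down, and medians below 0 with median-centred arrays. The neutrophil, eosinophil and mast cell list had a median of 0.05 and a mean of -0.12, and its median was -0.04 with median-centred arrays.

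In limma, 0 of 12393 genes passed an adjusted p of 0.05 between fiona and normal muscle, and 2626 had an unadjusted p under 0.05. With array set as a block 19 genes passed (3 higher, 16 lower), and 2 with the sex pattern also in the model. In array set 1 alone, with 2 fiona arrays, 29 passed (16 higher, 13 lower), and in array set 2 alone 5 passed, all lower. With array weights 54 genes passed (23 higher, 31 lower), and without fiona array 2, 974 passed (856 higher, 118 lower). The call was also changed without fiona array 1 (4 genes) and without normal array 5 (1 gene).

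**Figure D3:**
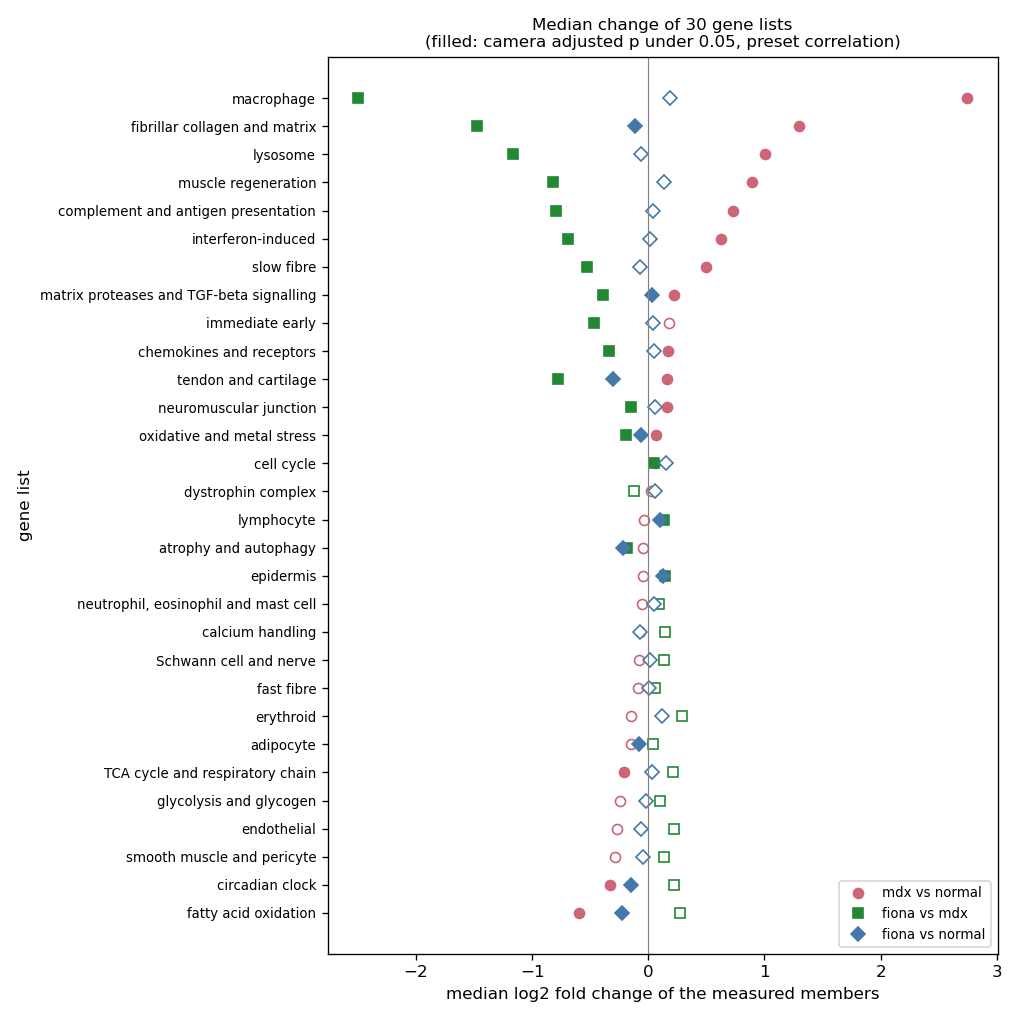
Median log2 difference of the measured members (horizontal axis) of 30 gene lists (vertical axis) in the 3 comparisons, filled where the camera adjusted p with the preset correlation was under 0.05. The macrophage list lies at 2.74 for mdx against normal, at -2.50 for fiona against mdx and at 0.19 for fiona against normal.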

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

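All tests of explanations in this part were chosen after the patterns had been seen.

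Between the array sets 2718 genes differed in limma, 250 of them at least 2-fold higher and 344 at least 2-fold lower in set 2. The sets were defined from these same values after removal of the group means. A high count, and arrays of every group in both sets, were thus in part fixed beforehand and are not separate evidence of a batch. Sex does not account for the sets, since 6 arrays broke the better matching of sex pattern and set. Shorter labelled RNA in set 2 may contribute: the 3' minus 5' difference of the transferrin receptor control was 1.297 log2 units higher in set 2 within groups (exact permutation p = 5e-04, 2000 labelings of 16 arrays), after mdx array 1, whose 3' signal lay at background, was left out because the test over every array had given 0.905 (exact permutation p = 0.05). The pyruvate carboxylase control moved the same way by 0.552 (exact permutation p = 0.00675). The 3' control of 18S ribosomal RNA measured 6.88 to 9.01 in set 1. It measured 9.36 to 13.5 in set 2 apart from mdx array 1, with 7.34, and this difference was not tested. Time of day at sampling stays open, because clock activators minus genes they drive differed by -0.733 between sets (exact permutation p = 0.0105) while the driven genes went both ways (Nr1d1 2.79 higher, Dbp 1.39 lower in set 2), and the design gives no biological difference between the sets to test. Of the activators, Arntl (0.05) and Npas2 (-0.11) hardly differed between set 2 and set 1, and Clock differed by -0.99.

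The sex pattern did not match the label male in 7 of 17 arrays, which were fiona arrays 1, 2, 3 and 5, mdx arrays 1 and 4 and normal array 6. A mixture of male and female RNA in equal parts is argued against for these arrays: in 8 arrays picked by Xist alone the median Eif2s3y differed by -3.244 log2 units from the lowest of the other 9, and in 7 of the 8 by -2.766 or lower, while mdx array 6, with Eif2s3y at 8.11 and Xist at 5.40 (other arrays of male pattern at most 2.475), did not. An exchange of samples between genotypes is argued against because 0 arrays were out of place on Dmd (at least 6.33 in normal and at most 3.53 in other arrays) or, for fiona and mdx arrays, in the position between the normal mean at 0 and the mdx mean at 1 (at most 0.182 in fiona and at least 0.773 in mdx arrays). Sex composition is argued against as the source of most differences between mdx and normal and between fiona and mdx muscle. With the sex pattern in the model, 95.52% (320 of 335) of the genes with at least 2-fold differences between mdx and normal muscle were still called, as were 420 of 438 between fiona and mdx muscle. Between fiona and normal muscle sex and genotype are poorly separated, because 4 of 5 fiona and 1 of 6 normal arrays had the female pattern. There, of 5 genes called at 2-fold or more with the array set block, only Dmd was still called with the sex pattern added. The Xist values above are from its probe set with the largest range. On another Xist probe set, fiona array 2 and mdx array 1 measured 3.08 each and mdx array 6 measured 3.01. Arrays of male pattern measured 2.83 to 3.12 there, and the other arrays of female pattern 5.34 to 9.04. Female animals among those labelled male may explain the pattern, and a share of female RNA in mdx array 6 stays open, neither of which was tested further.

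Of the genes called higher in fiona than in mdx muscle, 3948 differed by less than 2-fold, with a median difference of 0.151 and a median level of 2.78, and 82.7% lay under the median of all probe sets. A difference in array background may account for many of them: 15 unspiked bacterial control probe sets were higher in fiona than in mdx arrays by 0.1643 in the median over probe sets. Their array medians averaged 2.89 ± 0.09 in fiona (SD, n = 5), 2.70 ± 0.04 in mdx and 2.77 ± 0.08 in normal arrays (n = 6 each). That abundant transcripts raised in mdx muscle pulled other values down stays open, because the same genes differed between mdx and normal muscle by -0.0551, between the bounds set for and against it. A small rise of many genes with utrophin was not tested separately from background.

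Single arrays far from the others of their group were looked for in 216 groups of values, and 23 were found, where chance gives about 1 in 20, or 10.8. The value given is the gap to the nearest array divided by the range of the group. Fiona array 2 stood apart for Cav3 (higher, 0.781), Ces1d (higher, 0.715), Myh1 (lower, 0.792), Nos1 (lower, 0.797) and Sln (higher, 0.874). Fiona array 1 was lower for Col6a2 (0.871) and H2-Aa (0.863), and fiona array 5 was higher for Adam8 (0.802) and Timp1 (0.786). Among normal arrays, array 3 was lower for Acadvl (0.669), array 4 lower for Cav3 (0.705), array 6 higher for Ccl8 (0.791), array 5 higher for Dach2 (0.637) and array 2 lower for Postn (0.678). In mdx array 1, Jph1 was lower (0.705), the median correlation with other arrays was 0.946 (0.812), and the 5' control of Gapdh measured 11.3 where the nearest array had 14.2 (0.899). The sex pattern set apart fiona array 4 for Eif2s3y (0.864) and for a probe set of Xist (0.910), mdx array 4 for a pair of Xist probe sets (0.960 and 0.752), and normal array 6 for a pair of Xist probe sets (0.976 and 0.916).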

How the results depend on the processing

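The array set and sex pattern settings, the array set block without the first mdx array, and the block on array number with the mdx and normal arrays alone were chosen after seeing the data, as were the tests that use them, while other settings were planned, and where no cause is named the cause was not tested. Genes called between mdx and normal muscle, 578 with the deposited values, numbered 5289 with array weights (1108 higher and 4181 lower, where 399 were higher and 179 lower without), 293 at adjusted p under 0.01, 1238 with the array set block, 2565 in set 1, 272 in set 2, 1199 with sex pattern and array set, 1162 with the array set block and no first mdx array, and 441 to 692 without single arrays. At least 2-fold calls, 335, numbered 222 at adjusted p under 0.01 and 188 in set 2. Genes called between fiona and mdx muscle, 4818, numbered 892 with the filter on dim genes (fewer genes were tested), 1438 with median-centred arrays, 1905 with quantile normalization, 256 at adjusted p under 0.01 (50 higher, 206 lower), 110 in set 2, and 3191 (without fiona array 5) to 5342 without single arrays. At least 2-fold calls, 438, numbered 190 at adjusted p under 0.01 and 83 in set 2. Genes called between fiona and normal muscle, 0 with the deposited values and 2626 at an unadjusted p under 0.05 in limma, numbered 1 with the filter on dim genes, 1 with the mean of probe sets, 1 with every probe set tested, 1 with an intensity trend and robust prior, 54 with array weights, 19 with the array set block, 29 in set 1, 5 in set 2, 2 with sex pattern and array set, 32 with the array set block and no first mdx array, and 0 to 974 without single arrays (974 without fiona array 2, 4 without fiona array 1, 1 without normal array 5). The at least 2-fold counts were 1, 1, 1 and 1 for the first 4 of these settings, then 25, 5, 13, 3, 1 and 12, and 0 to 42 without single arrays (42 without fiona array 2, 3 without fiona array 1, 1 without normal array 5). Opposite calls, 454, numbered 4112 with array weights, 184 at adjusted p under 0.01, 868 with the array set block, 2138 in set 1, 93 in set 2, 868 with sex pattern and array set, 787 with the array set block and no first mdx array, and 350 to 583 without single arrays. Set 1 and set 2 hold fewer arrays. The array weights ranged from 0.205 for fiona array 5 to 5.30 for normal array 4. Lists called numbered 3 (of 16), 3 (of 17) and 0 (of 10) with an estimated correlation for mdx against normal, fiona against mdx and fiona against normal; for the last they also numbered 0 with fry, 5 with the filter on dim genes and 1 with quantile normalization. Without single arrays they numbered 14 to 18, 15 to 18 and 7 to 15. The reversed share of 0.906 stayed between 0.873 and 0.942 under every setting run, less than the spread over fiona arrays (SD 0.0764) away. Utrn reversed between fiona and mdx muscle from -0.41 to 1.25 (adjusted p = 0.0461) with the mean of probe sets, which brings in the 2 probe sets that follow the transgene. Of the named genes, 3 calls between fiona and mdx muscle were lost with median-centred arrays and 1 with quantile normalization, and 0 between mdx and normal muscle under either. A linear pseudocount was not run because the values are log2.

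Array numbers followed the array sets for mdx and normal arrays, where 6 of 6 pairs with the same number lay in the same set, with residual correlations of 0.0876 to 0.605 (5 of 6 over 0.1), and for 1 of the 6 the other group's most similar array had the same number. With fiona arrays 2 of 5 pairs lay in the same set, and correlations were -0.423 to 0.295 for mdx and fiona (1 of 5) and -0.488 to 0.483 for normal and fiona (1 of 5). A block on the number gave 509 genes (185 higher, 324 lower, 269 at least 2-fold) between fiona and mdx muscle, 1 between fiona and normal muscle, 300 opposite calls, and 528 between mdx and normal muscle, or 798 with the mdx and normal arrays alone. Under it 5 named calls between mdx and normal and 11 between fiona and mdx muscle did not pass, with adjusted p of 0.0504 to 0.0882 and 0.0507 to 0.0675. Between fiona and mdx muscle, 2 calls among the Dmd and Utrn probe sets and 2 list calls were also lost under this block. One further list call, 1 in number, was gained.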

Other observations

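The genes of this and the next paragraph, the test of the fed state and the tests within array sets were chosen after values had been seen, while the tests of the size of changes and of slow muscle were written first. A group of genes was lower in mdx than in normal muscle and stayed at the mdx level in fiona muscle. Rragd, a GTPase of amino acid sensing, measured 7.36 ± 0.60 in normal (SD, n = 6), 5.80 ± 0.75 in mdx (n = 6) and 5.81 ± 0.49 in fiona muscle (n = 5). Asb15, a muscle gene of the ankyrin repeat and SOCS box family, measured 3.94 ± 0.52, 2.77 ± 0.16 and 2.84 ± 0.06. Cyp2e1, a cytochrome P450 induced by ketones, measured 5.71 ± 0.80, 4.06 ± 0.82 and 3.82 ± 0.07. Ucp3, Pdk4 and Scd1 measured 6.97, 10.9 and 7.73 in mdx and 6.91, 10.7 and 7.83 in fiona muscle, against 8.89, 12.5 and 9.27 in normal muscle. Of the Asb15 values, those of 3 of 6 mdx and 4 of 5 fiona arrays lay at or under the level of the unspiked controls. Outside this group, Glul, glutamine synthetase, measured 9.90 ± 0.92 in normal, 9.41 ± 0.44 in mdx (adjusted p = 0.432) and 8.53 ± 0.65 in fiona muscle.

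With array set as a block, 5 genes were called between fiona and normal muscle at 2-fold or more, all lower in fiona muscle. They were Dmd (-3.18, adjusted p = 0.00478), Ucp3 (-1.87, 0.0272), Rragd (-1.45, 0.0146), Glul (-1.26, 0.0237) and Asb15 (-1.11, 0.0428; at least 1.04 lower in the means, against the control level). With the sex pattern also in the model, since 4 of 5 fiona and 1 of 6 normal arrays had the female pattern, Dmd was called (-3.71, adjusted p = 0.000659), and Ucp3 (-1.67, 0.126), Rragd (-1.24, 0.0900), Glul (-1.14, 0.125) and Asb15 (-1.07, 0.134) were not. The differences of Cyp2e1 (-1.90, adjusted p = 0.121), Pdk4 (-1.73, 0.136) and Scd1 (-1.43, 0.195) did not pass with the block alone.

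Because Ucp3 and Pdk4 are induced by fasting, mdx and fiona animals may have been in a more fed state than normal animals. A more fed state would not account for the low level of Scd1, a lipid synthesis gene. Over 21 other fasting-induced genes, the median difference between fiona and normal muscle with the array set block was -0.3851 (range -1.70 to 0.40, SD 0.52), with 18 of 21 lower. Between mdx and normal muscle the median was -0.59, with 17 of 21 lower, the highest being Angptl4 (0.44) and Gadd45a (0.36). The fiona value of -0.3851 lies between the bounds set for and against the hypothesis. Several of these genes belong to lists already seen to be lower, and feeding is not given in the labels, so the question stays open.

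Genes lower in mdx muscle recovered less in fiona muscle than genes higher in mdx muscle, and a smaller size of the lower changes was tested as a candidate explanation. Dmd was not left out of the lower genes. Among genes changed between 2-fold and 4-fold in the selecting arrays, the reversed share was 0.972 for higher and 0.559 for lower genes. The difference was 0.3988 in the median and above 0 in 42 of the 42 divisions with at least 5 such genes in each direction (range 0.0611 to 6.07), which argues against size as the whole explanation. The divisions reuse the same arrays and share all fiona arrays, so their agreement is not replication.

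In mdx array 1 the slow fibre genes Myl2 (8.07, other mdx arrays 3.25 to 5.22) and Tnnt1 (10.1, other mdx arrays 5.95 to 9.81) were high, and tissue of a neighbouring slow muscle could be a source. The median of 8 other slow fibre genes in that array lay 0.84 above the mean of the other 5 mdx arrays, where the highest other mdx array reached 0.679. Since 0.84 lies between the bounds set before, the hypothesis was neither excluded nor borne out. In that array 7 of the 8 genes lay within the range of the other mdx arrays, and Myh7 lay above it (3.90, other mdx arrays 2.25 to 3.27).

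Counts were compared with those from 100 divisions of the same arrays, the real one included, and the number of divisions with a count as large is given. For mdx against normal it was 2 for the 578 genes called and 2 for the 335 at least 2-fold calls, in both cases because the division by array set gave more (1056 and 398), while the next highest gave 37 and 26. For divisions within array sets it was 1 (1238 genes, highest other 129). Chance is unlikely for these counts, though 100 divisions do not exclude it. For the 16 lists it was 8 (highest other 19, median of the others 8), and chance cannot be excluded. For fiona against mdx it was 1 for the 4818 genes (highest other 4467). It was 3 for the 438 at least 2-fold calls (highest other 513, the division by array set, then 456). It was 3 for the 17 lists (highest other 18, median of the others 7) and 1 within array sets (5398 genes, highest other 359). These low numbers make chance less likely but do not exclude it. Except within array sets, other divisions came near the real counts or passed them. For the 454 opposite calls it was 1 (highest other 143), which makes chance unlikely. For fiona against normal, with 0 genes called (highest other 1288, the division by array set, then 512) and 0 at least 2-fold calls (highest other 554, the division by array set, then 233), each of the 100 divisions reaches the real count of 0, so these counts say nothing about chance. For the 10 lists it was 25 (highest other 16, median of the others 6), and chance cannot be excluded. The array sets were defined from these same values, so the high counts of the division by array set were in part fixed beforehand. Within array sets it was 1 for the 19 genes called (highest other 3), which makes chance less likely but does not exclude it. The sets were defined from residuals of the real groups and kept for all divisions. This may favour the real grouping in each count within array sets. The block was also chosen after the data were seen.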
